A study of Mus musculus with 156 samples.

How the data were processed

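The samples were mouse embryonic stem cells in 4 lines, a WT control, a Firre KO control and, for each, a line with a doxycycline-inducible Firre transgene. Per the labels' protocols, cells grew in medium with serum, LIF, the MEK inhibitor PD0325901 and the GSK3 inhibitor CHIR99021. Doxycycline was added on the day after seeding, after a change of medium. RNA was extracted with TRIzol and a column kit, and poly(A) libraries were made with a TruSeq RNA v2 kit, which does not mark strand. Samples were randomized over HiSeq lanes in multiples of 12, per the labels' protocols. All samples received doxycycline except those of 0 min, so doxycycline, the age of the medium and time in culture are not separated in the control lines. Lanes, culture days and batches are not named in the labels, and what a replicate is, a culture dish or a separate culture, is not given.

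Gene-level expected counts and TPM were deposited for 156 libraries and 40914 genes. Per the submitters' processing notes, reads were processed with Salmon 1.5.2 on mm10. How transcripts were summed to genes was not given. In the deposited expected counts 76% of values were exactly whole, and 7313 genes had no count. The deposited TPM values, so named per the file headers, summed to between 924452 and 947484 per library, so the scaling covered features outside the table. TPM served to describe levels and the expected counts served every test. TPM and fold changes of one gene can differ, because the first corrects for transcript length and the second for library composition. Gene positions came from GENCODE M21 (mm10), in which 40140 gene identifiers matched with their version. Mitochondrially encoded genes took 3.36 to 5.44% of the counts of a library.

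Expected counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3, separately for the courses. Genes were kept by filterByExpr with its default settings (minimum count 10, minimum total 15), libraries were scaled by TMM, and negative binomial models were fitted with robust quasi-likelihood dispersions. The long course had 1 coefficient per line and time. The short course had, for each line, an intercept and a natural cubic spline of time with 3 df, and its 0 min and per-time contrasts came from a fit with 1 coefficient per line and time. The contrasts were KO control against WT control at 0 min, transgene line against control at 0 min, the change from 0 min in each control, the response to the transgene (change in the transgene line minus change in its control) in the KO background (rescue) and in the WT background (overexpression), and the difference between those responses. Responses were F tests with 4 df in the long and 3 df in the short course, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fold change of such a test was that of the time with the largest size in the long course and the mean over the 11 times after 0 min in the short course. Its standard error was the size of the log2 fold change over the square root of the F statistic of that contrast. A library counted as showing the direction of a response when its value lay, in log2 CPM, on the side of the fold change, relative to 0 min and to the mean change of the control at the same time. The libraries of a response share the means at 0 min and those of a time share the control mean, so they do not count as independent.

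Named genes were Firre, the 10 genes with the largest log2 fold change each way among those passing in the long KO comparison and in the rescue and overexpression of both courses, and the 5 each way in the others, with a mean CPM of at least 1 and a symbol that is not a provisional one, plus at most 4 passing members of each gene list by smallest adjusted p. CPM was computed with edgeR. Gene lists numbered 29: naive pluripotency, general pluripotency, formative and primed epiblast, 2-cell-like state, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, germline genes, imprinted genes, fibroblast or feeder, p53 targets, integrated stress response, heat shock, interferon response, mitochondrial protein quality control, mitochondrially encoded genes, glycolysis and hypoxia, cholesterol synthesis, immediate early genes, FGF/ERK targets, Wnt/beta-catenin targets, G1/S and G2/M cell cycle, replication-dependent histones, X inactivation centre, neighbours of the Firre locus and trans contacts of Firre, with nuclear matrix and chromatin partners of Firre. They were tested with camera of limma 3.58.1 on the counts, in the fit with 1 coefficient per line and time, with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and with fry as alternatives. For responses over several times the mean over the times after 0 min was tested. The tests, named-gene rule, lists and most alternatives were fixed before the data were examined.

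The scripts were tested on simulated counts with 200 genes changed. The changed genes had a mean of at least 50 counts, and the simulated libraries varied independently of each other. The shares below thus do not cover genes with fewer counts, outlying libraries or libraries that deviate together. Of 1.5-fold changes, 97% were called for the long KO comparison, 79% for the long rescue and 63% for the long difference of responses (17223 genes), and 84%, 84% and 66% for those of the short course (17654 genes). Of 2-fold changes, 99% were called for the long rescue and 97% for the short rescue. Unchanged genes made up 5.8%, 9.2% and 8.8% of the calls of those tests in the long course and 6.7%, 5.2% and 4.9% in the short course. Alternatives chosen before were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter or a minimum mean of 50 counts, a minimum log2 fold change of 0.58, fits on only the lines compared, the replicate number as a block, each replicate number left out, splines with 5 df and 1 coefficient per time. Alternatives that leave out times or single libraries were chosen after seeing the data. Adjusted p values measure the spread between these libraries of 1 line per genotype and transgene, so differences between lines hold for these lines.

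Reads of near-identical gene copies, such as those of the Zscan4 and Pramel families, could be split between members in ways the counts do not show, so their values are uncertain. Without strand, reads of overlapping or antisense genes cannot be told apart. Genes with provisional symbols were tested and counted but are not named. A gene that the rule picked is withheld and is not reported here. No sample or table was left out of the tests.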

Results

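RNA abundance was measured by RNA-seq in mouse embryonic stem cells after doxycycline, in 4 lines. A wild-type (WT) and a Firre knockout (KO) line served as controls, and each had a matched line with a doxycycline-inducible transgene for the long noncoding RNA Firre. The long course sampled 0, 720, 1440, 2880 and 5760 min with 3 replicates per group. The short course sampled 12 times from 0 to 330 min at 30-min steps with 2 replicates per group. The 156 libraries formed 68 groups, 60 libraries in the long course and 96 in the short one. Total counts per library ranged from 18961799 to 47948630 in the long course and from 19013652 to 37195019 in the short course. The filter left 17565 genes to test in the long course and 18009 in the short course. Fold changes are log2 values with their standard error. A response to the transgene is the change from 0 min in the transgene line minus that in its control. It is given at the time of largest size in the long course and as the mean over the 11 times after 0 min in the short course.

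Firre itself (ENSMUSG00000085396.7, chromosome X, 50555744 to 50635321, mm10) followed the labels in every group. In the long course it stood at 24.2 ± 0.582 TPM (SD, n = 3) in the WT control at 0 min and at 0.390 ± 0.142 TPM in the KO control, a log2 fold change of -7.62 ± 0.10 (edgeR adjusted p = 2.85e-66). The short course gave -5.43 ± 0.17 (edgeR adjusted p = 1.75e-31, n = 2). In the KO transgene line Firre went from 1.66 ± 0.393 TPM at 0 min to 136 ± 8.79 at 30 min and 465 ± 8.14 at 120 min, and stood at 172 ± 1.15 at 330 min (SD, n = 2). In the WT transgene line it went from 43.5 ± 2.90 to 423 ± 1.15 and 1162 ± 110 TPM, and to 293 ± 14.3 at 330 min. Against 0 min of the same line, the log2 fold change at 120 min was 8.06 ± 0.16 in the KO background and 4.21 ± 0.11 in the WT background (edgeR adjusted p = 1.17e-41 and 1.09e-35). The WT control lay between 20.1 and 26.5 TPM over the short course. At 5760 min of the long course the level was 39.0 ± 1.46 TPM in the KO transgene line and 65.3 ± 3.74 in the WT transgene line (SD, n = 3). Before doxycycline the transgene lines already held more Firre than their controls, by 1.35 ± 0.28 in the KO background and 0.31 ± 0.04 in the WT background (edgeR adjusted p = 6.81e-04 and 6.68e-08). The former missed the threshold without replicate 2 (edgeR adjusted p = 0.119). At 0 min of the long course Firre stood at 0.895 ± 0.267 TPM in the KO transgene line, against 0.390 ± 0.142 in its control. In the WT transgene line it stood at 46.1 ± 0.546 TPM, against 24.2 ± 0.582 in its control (SD, n = 3). The difference in the WT background was thus larger by TPM than by the fold change of the counts.

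**Figure D1:**
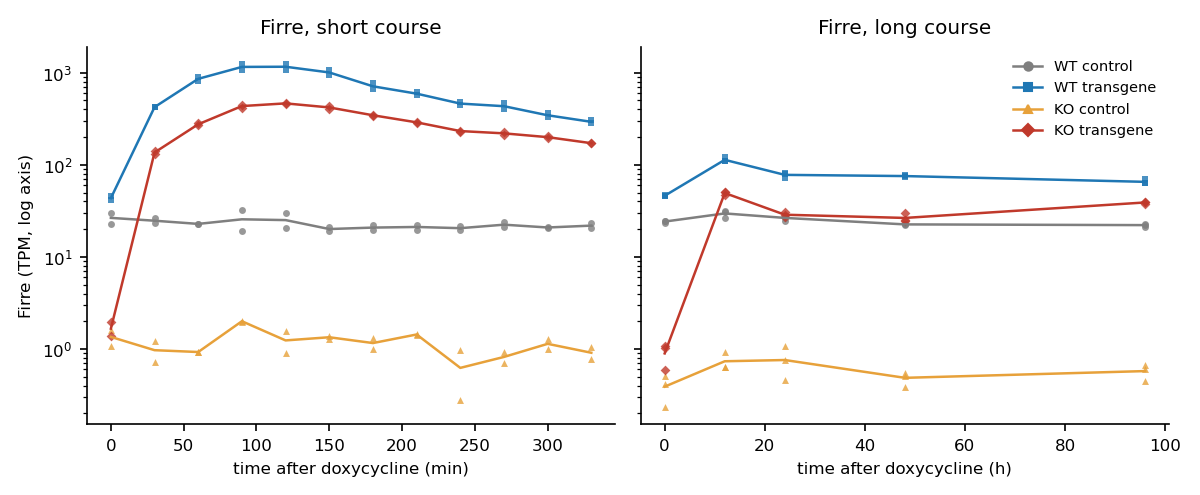
Firre abundance in TPM (log axis) against time after doxycycline for the 4 lines, in min in the short course and in h in the long course. Points are libraries and lines join group means. The KO transgene line reached 465 TPM and the WT transgene line 1162 TPM at 120 min.

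The KO control was compared with the WT control before doxycycline, with 1 control line per genotype. A difference can thus come from the line and is not shown to depend on Firre. Lines of the same genotype differed at 0 min of the long course too, in 2312 genes between the WT lines and 622 between the KO lines. Usp26 differed between the WT lines, as given below. Suz12, a subunit of Polycomb repressive complex 2, was higher in the KO control in the long and the short course, by 0.77 ± 0.03 and 0.26 ± 0.07 (edgeR adjusted p = 1.54e-33 and 0.0189, in 3 of 3 libraries and 2 of 2 libraries), and Usp26, an X-linked deubiquitinase gene, by 1.56 ± 0.07 and 0.76 ± 0.12. The developmental regulator Meis2 was lower in the long course (-1.56 ± 0.18), as was the growth factor gene Fgf7 (-1.72 ± 0.24). In the short course the aryl hydrocarbon receptor targets Cyp1a1 and Cyp1b1 were higher by 5.10 ± 0.24 and 2.87 ± 0.27, and the Wnt target Sp5 and the VEGF receptor gene Kdr were lower, at -1.27 ± 0.17 and -1.23 ± 0.23. Some genes passed in the same direction in both courses with a log2 fold change of at least 0.58 in each. Meis2 and Usp26 were among them. Fgf7, Cyp1a1, Cyp1b1, Sp5 and Kdr were not, so their differences did not repeat at that size in the other course. In all, 6171 genes differed in the long course (2898 higher and 3273 lower, n = 3 against 3), of which 1391 had a log2 fold change of at least 0.58, and 1353 in the short course (615 higher and 738 lower, n = 2 against 2). The courses shared 711 genes, 248 higher in both (102.3 for independent lists), 273 lower in both (138.8) and 190 in opposite directions. As the mean over all times of each course, with more libraries in the contrast, they shared 5067 genes. Of these, 1850 were higher in both (996.2 for independent lists), 1862 lower in both (1142.3) and 1355 in opposite directions. Because the KO control changed between 720 and 1440 min of the long course, the comparison was also made, after the data were seen, as the mean over 1440 to 5760 min. It called 6546 genes and shared 3864 of those at 0 min, 3664 in the same direction.

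Counts of list members passing are over all genes tested and then adjusted over the list alone. Of the lists named here, imprinted genes and p53 targets also differed at 0 min between lines of the same genotype, as given below. Imprinted genes were higher in the KO control at 0 min of the long course (12 higher and 2 lower of 23, 13 and 3 adjusted over the list alone; camera adjusted p = 4.43e-08). The paternally expressed Mest and Peg3 were higher by 0.89 ± 0.04 and 0.49 ± 0.03. Genes of the 2-cell-like state were lower (2 higher and 12 lower of 14, 2 and 12 adjusted over the list alone; camera adjusted p = 1.29e-13), among them Zscan4d (-0.90 ± 0.06). Members of that family share near-identical copies, so the split of reads between them is uncertain. The p53 targets were lower (1 higher and 10 lower of 16, 1 and 10 adjusted over the list alone; camera adjusted p = 0.00727), led by the kinase gene Plk2 (-0.65 ± 0.05) and the cell-cycle inhibitor Cdkn1a (-0.35 ± 0.04). Dazl, an RNA-binding protein gene of germ cells, was higher by 0.85 ± 0.04 in the long course and the synaptonemal complex gene Sycp3 by 0.79 ± 0.15 in the short course. Germline genes were higher as a list in both (short course, 7 higher and 0 lower of 15, 9 and 0 adjusted over the list alone; camera adjusted p = 1.46e-07; long course, camera adjusted p = 0.00950, and adjusted p = 0.0630 with an estimated correlation). FGF/ERK targets were lower in the short course (0 higher and 7 lower of 14, 0 and 7 adjusted over the list alone; camera adjusted p = 1.25e-05, and adjusted p = 0.0542 with an estimated correlation). The transcription factor gene Etv4 stood at -0.55 ± 0.09. Of 15 genes near the Firre locus, 7 were higher and 1 lower in the long course, the same adjusted over the list alone (camera adjusted p = 0.0817).

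The transgene lines were compared with their controls at 0 min because lines can differ before induction. In the KO background the Y-linked genes Ddx3y, Uty and Eif2s3y were higher in the transgene line, by 1.10 ± 0.05, 1.04 ± 0.07 and 1.01 ± 0.06, and the X-linked ubiquitin ligase gene Mid1 by 1.26 ± 0.06 (edgeR adjusted p = 6.74e-29, 6.41e-19, 3.09e-25 and 1.82e-27, n = 3 against 3). At 0 min of the short course Ddx3y stood at 41.9 ± 1.08 TPM in the KO transgene line and 38.2 ± 0.987 in the KO control, and Eif2s3y at 71.1 ± 9.52 and 77.7 ± 4.5 (SD, n = 2), a difference that was not tested. In the WT background Mid1 was higher by 2.46 ± 0.07, and Wdfy1, which encodes an endosomal protein, and Usp26 were lower, at -1.52 ± 0.06 and -1.40 ± 0.09 (edgeR adjusted p = 2.90e-43, 5.29e-35 and 1.78e-22). 622 genes differed in the KO background (322 higher, 300 lower) and 2312 in the WT background (1269 higher, 1043 lower). Without replicate 1, 2 or 3 of every group the counts were 319, 248 and 297 in the KO background and 1455, 1090 and 1328 in the WT background. Imprinted genes were lower in the KO transgene line (0 higher and 8 lower of 23, 0 and 9 adjusted over the list alone; camera adjusted p = 4.83e-12; Peg3 -0.34 ± 0.03). In the WT transgene line p53 targets were lower (1 higher and 9 lower of 16, 1 and 11 adjusted over the list alone; camera adjusted p = 9.50e-13; Mdm2, the p53 ubiquitin ligase gene, -0.42 ± 0.03). Genes of the integrated stress response were higher there (11 higher and 2 lower of 20, 12 and 2 adjusted over the list alone; camera adjusted p = 2.62e-05; the asparagine synthetase gene Asns 0.20 ± 0.03).

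The rescue comparison asks what changes when Firre is put back into knockout cells. In the long course the largest rises were those of Rapgef4, a cAMP-activated exchange factor for Rap (3.57 ± 0.41 at 5760 min), the hydrogen peroxide-forming oxidase Duox1 (3.25 ± 0.39 at 1440 min), the astrocyte filament gene Gfap (2.82 ± 0.37 at 720 min), Shf, an SH2-domain adaptor (2.58 ± 0.10 at 5760 min), the lipocalin Apod (2.42 ± 0.17) and the adhesion receptor gene Adgrg1 (2.41 ± 0.20). Their edgeR adjusted p values were 1.12e-08, 1.12e-08, 1.14e-07, 1.17e-30, 7.29e-20 and 1.44e-15, and Shf and Duox1 were higher in 12 of 12 libraries after 0 min each. Among the largest falls were those of the actin regulator gene Cap2 (-1.26 ± 0.24 at 1440 min) and of Cemip, which acts in hyaluronan turnover (-1.18 ± 0.15 at 5760 min; edgeR adjusted p = 1.43e-05 and 2.59e-09). The insulin-responsive glucose transporter gene Slc2a4 fell by 1.37 (edgeR adjusted p = 0.0148, and 0.581 without replicate 2). The test over all times called 2024 genes (976 higher and 1048 lower), 470 of them by a log2 fold change of at least 0.58. The counts were 150 at 720 min, 1134 at 1440 min, 849 at 2880 min and 940 at 5760 min. Between 720 and 1440 min the KO control itself changed in 6761 genes, and the step was large in the other lines too. It was 6923 genes in the KO transgene line, 5365 in the WT control and 7338 in the WT transgene line. Without replicate 1, 2 or 3 of every group the test called 1271, 742 and 1023 genes, and at 720 min 73, 41 and 75. At 1440 min it called 679, 440 and 561, at 2880 min 501, 335 and 433 and at 5760 min 487, 522 and 449.

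Naive pluripotency genes fell in the long rescue (1 higher and 8 lower of 16, 2 and 8 adjusted over the list alone; camera adjusted p = 6.00e-11). The transcription factor genes Klf4 and Tbx3 stood at -0.43 ± 0.05 and -0.35 ± 0.05 and the 5-methylcytosine dioxygenase gene Tet2 at -0.37 ± 0.04. At 720 min alone, a choice made after seeing the data, the list was lower too (median -0.10, camera adjusted p = 1.01e-09). General pluripotency genes were lower too (camera adjusted p = 1.18e-06 at 720 min; over all times 1 higher and 7 lower of 12, 1 and 8 adjusted over the list alone; camera adjusted p = 0.00474). Trophoblast genes rose (8 higher and 1 lower of 13, 9 and 1 adjusted over the list alone; camera adjusted p = 2.50e-11; 0.00442 at 720 min). Among them were the keratin gene Krt18 (1.06 ± 0.11) and the transcription factor gene Ascl2 (1.59 ± 0.15). Imprinted genes rose (10 higher and 1 lower of 23, 11 and 1 adjusted over the list alone; camera adjusted p = 4.82e-15; 0.0218 at 720 min). They were lower in the KO transgene line than in its control at 0 min, and those libraries are subtracted in the response. The rise is thus not separate from that earlier difference. For the imprinted Peg3 the rescue was 0.81 ± 0.04, where the KO control had a change of -0.68 ± 0.03 over its own course. Germline genes (7 higher and 0 lower of 15, 8 and 1 adjusted over the list alone; camera adjusted p = 1.92e-06) and formative and primed epiblast genes (5 higher and 0 lower of 13, 7 and 0 adjusted over the list alone; camera adjusted p = 9.44e-06) rose over all times. At 720 min they did not pass (camera adjusted p = 0.685 and 0.682). The germ-cell gene Dazl stood at 1.13 ± 0.06 and the DNA methyltransferase gene Dnmt3b at 0.42 ± 0.05. Genes of the integrated stress response fell (1 higher and 5 lower of 20, 1 and 8 adjusted over the list alone; camera adjusted p = 3.61e-04; Asns -0.34 ± 0.04). Fibroblast or feeder genes were higher as a list (1 higher and 1 lower of 9, 2 and 2 adjusted over the list alone; camera adjusted p = 0.00774; the collagen gene Col5a1 1.01 ± 0.09 and, lower, the cytoskeletal gene Tagln -0.47 ± 0.15, for which the edgeR adjusted p was 0.156 without replicate 2).

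The overexpression comparison asks what more Firre does in cells that have it. In the long course Rapgef4 (5.71 ± 0.53), Duox1 (4.90 ± 0.43), Adgrg1 (3.78 ± 0.23), Apod (2.67 ± 0.17) and Shf (2.57 ± 0.12) rose here too, and with them the eosinophil peroxidase gene Epx (2.27 ± 0.29), the cholesterol ester hydrolase gene Nceh1 (1.53 ± 0.08) and the P-cadherin gene Cdh3 (1.48 ± 0.09). Their edgeR adjusted p values ran from 1.69e-26 for Shf to 1.00e-08 for Epx, with Shf, Duox1 and Nceh1 higher in 12 of 12 libraries each. Genes that fell included Pramel7, which acts in ground-state pluripotency (-1.19 ± 0.17), the microRNA-binding protein gene Lin28a (-0.54 ± 0.04) and the cyclin gene Ccnd1 (-0.46 ± 0.05; edgeR adjusted p = 1.32e-05, 1.39e-16 and 1.29e-10). The largest falls by size, those of small structural RNAs such as Rn7s1 (-5.72 ± 1.62), came with a single library. In replicate 3 of the WT control at 1440 min Rn7s1 stood at 1541 TPM, against 14.6 and 21.9 in the other replicates. Without that library the fold change of Rn7s1 was -0.58 (edgeR adjusted p = 0.946) and the test called 1662 genes in all. The test called 1720 genes (731 higher and 989 lower), and 102, 325, 449 and 1446 at 720, 1440, 2880 and 5760 min. Without replicate 1, 2 or 3 of every group it called 1658, 297 and 644. At 720 min it then called 43, 38 and 43, at 1440 min 156, 90 and 122, at 2880 min 209, 117 and 169 and at 5760 min 1530, 400 and 535. With no filter on low counts the count at 720 min was 216. General pluripotency genes fell (0 higher and 8 lower of 12, 0 and 9 adjusted over the list alone; camera adjusted p = 4.99e-08). Naive pluripotency genes were lower (2 higher and 6 lower of 16, 3 and 11 adjusted over the list alone; camera adjusted p = 0.0352, and adjusted p = 0.0797 with an estimated correlation), and at 720 min alone they had a median of -0.12 (camera adjusted p = 6.05e-10). Trophoblast genes rose (5 higher and 0 lower of 13, 7 and 0 adjusted over the list alone; camera adjusted p = 9.23e-04). The p53 targets rose too (7 higher and 1 lower of 16, 9 and 1 adjusted over the list alone; camera adjusted p = 1.51e-04), but not at 720 min (camera adjusted p = 0.872). They were lower in the WT transgene line at 0 min, and those libraries are subtracted in the response. The rise is thus not separate from that earlier difference.

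In the short course, which follows the first hours of induction, the rescue called 328 genes (136 higher and 192 lower). The count was 572 with DESeq2, 1131 with no filter on low counts, 105 in a fit on only the lines compared and 171 with 1 coefficient per time. Duox1 rose by 2.73 ± 0.45, Shf by 1.44 ± 0.15, Apod by 0.85 ± 0.27, Adgrg1 by 1.16 ± 0.26, Nceh1 by 0.58 ± 0.10 and the activin-binding protein gene Fst by 0.53 ± 0.10 (edgeR adjusted p = 4.00e-13, 1.37e-23, 5.27e-09, 4.98e-14, 7.15e-23 and 4.48e-14). Duox1 was higher in 22 of 22 libraries after 0 min and Shf in 21 of 22 libraries. DESeq2 gave Duox1 a log2 fold change of 2.91 in this comparison but no adjusted p. The Nodal inhibitor gene Lefty1 fell by 0.55 and Id4, which encodes an inhibitor of DNA binding, by 0.45 (edgeR adjusted p = 2.84e-05 and 0.00812), the latter not without replicate 1 or 2 (0.191 and 0.125). Naive pluripotency genes fell as a list (0 higher and 4 lower of 16, 0 and 6 adjusted over the list alone; camera adjusted p = 4.95e-06). The pluripotency transcription factor gene Nanog stood at -0.18 ± 0.05, lower in 22 of 22 libraries (edgeR adjusted p = 9.73e-05). Firre itself, at 7.57 ± 0.41 over the times after 0 min, was called at each of those times against its control but not by the smooth-curve test (edgeR adjusted p = 0.238). The adjusted p for it was 7.93e-08 by DESeq2, and by edgeR 8.36e-41 with no filter on low counts, 1.18e-15 with 1 coefficient per time and 0.0319 with a spline of 5 df. Calls per time stayed at or below 5 to 150 min, peaked at 735 at 180 min and lay between 19 and 114 afterwards. Without replicate 1 of the KO transgene line at 180 min 29 genes were called at 180 min, and without replicate 2 of that group 1272. The library left there is assumed to vary like the other groups. The smooth-curve test called 210 genes without replicate 1 of that group, 235 without replicate 2 of it and 148 without the 180 min libraries. It called 52 without replicate 1 and 325 without replicate 2 of every group, and 5 from the times to 150 min.

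Overexpression in the short course called 126 genes (91 higher and 35 lower). The count was 469 with no filter on low counts, 216 in a fit on only the lines compared (115 higher and 101 lower), 46 with 1 coefficient per time and 82 with a spline of 5 df. Duox1 rose by 2.63 ± 0.46, Adgrg1 by 2.26 ± 0.27, Shf by 1.71 ± 0.13, Kdr by 1.36 ± 0.21, Apod by 1.09 ± 0.24 and Pde6d, a carrier of prenylated proteins, by 0.77 ± 0.11 (edgeR adjusted p = 1.25e-20, 1.41e-30, 1.52e-30, 3.42e-21, 6.82e-16 and 9.89e-16). The FGF-binding protein gene Fgfbp3 rose by 1.94 ± 0.30 (edgeR adjusted p = 0.00877, and 0.382 and 0.112 without replicate 1 and 2) and was not among the genes called in the rescue. The difference between those responses did not pass (-1.98 ± 0.46, edgeR adjusted p = 0.523). Nanog (-0.23 ± 0.05, lower in 22 of 22 libraries), the Nodal co-receptor gene Tdgf1 (-0.16 ± 0.05) and Sox2, another pluripotency transcription factor gene (-0.20 ± 0.05), fell (edgeR adjusted p = 5.45e-11, 1.94e-06 and 1.26e-04), Sox2 not without replicate 2 (0.857). In the WT transgene line Nanog went from 642 ± 5.59 TPM at 0 min to 591 ± 9.90 at 330 min, and in the WT control from 643 ± 5.26 to 713 ± 2.84 (SD, n = 2). Naive pluripotency genes fell as a list (0 higher and 4 lower of 16, 0 and 4 adjusted over the list alone; camera adjusted p = 7.16e-08). General pluripotency genes fell too (0 higher and 2 lower of 12, 0 and 4 adjusted over the list alone; camera adjusted p = 0.00283). Calls per time rose from 1 at 30 min to 6 at 150 min, 21 at 180 min and 36 at 330 min. The smooth-curve test called 799 genes without replicate 1 and 51 without replicate 2 of every group, and 5 from the times to 150 min.

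Genes called in all 4 responses to the transgene numbered 43, of which 34 were higher in all of them, 5 lower in all and 4 mixed. Shf (ENSMUSG00000033256.14, chromosome 2, 122348892 to 122369162) was the earliest, called at 90 min in both backgrounds. It rose from 8.58 ± 1.02 TPM at 0 min to 18.2 ± 1.29 at 90 min and 45.6 ± 1.68 at 330 min in the WT transgene line, and from 6.36 ± 0.516 to 15.2 ± 1.12 and 36.8 ± 5.66 in the KO transgene line, against 7.36 ± 0.474 and 9.05 ± 1.13 TPM at 330 min in the WT and KO controls (SD, n = 2). Duox1 (ENSMUSG00000033268.8, chromosome 2, 122315672 to 122347972), its neighbour on the other strand with the 3' ends facing each other, was called from 120 min in the KO background (2.97 ± 0.55, edgeR adjusted p = 0.00585) and from 180 min in the WT background (2.93 ± 0.54, edgeR adjusted p = 0.00153). The libraries do not mark the strand. Nceh1 rose from 6.16 ± 0.0391 to 14.7 ± 1.26 TPM in the WT transgene line and from 7.51 ± 1.03 to 15.7 ± 1.02 in the KO transgene line. Others higher in all 4 were Cdh3, Fst, Adgrg1, Apod, Rapgef4, Gfap and Kdr, and those lower in all 4 included Sox2 and Tbx3. The rescue and overexpression of the short course shared 62 genes where independent lists would share 2.3: 47 higher in both (0.7 for independent lists), 13 lower in both (0.4) and 2 opposite. No library entered both. In the long course they shared 635 (198.2 for independent lists), of which 148 went in opposite directions. The long and short rescue shared 159 genes (37.7 for independent lists) and the long and short overexpression 74 (12.5).

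**Figure D2:**
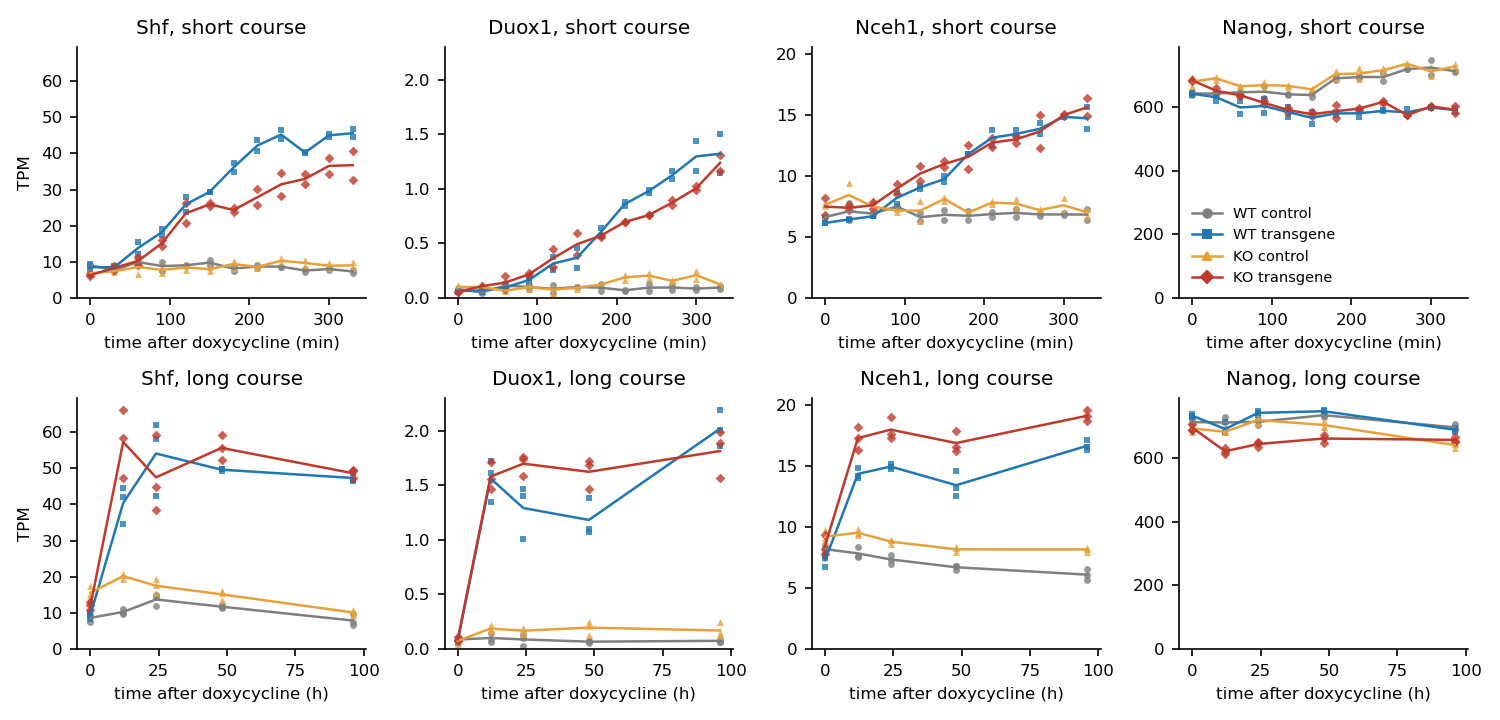
Abundance of Shf, Duox1, Nceh1 and Nanog in TPM against time after doxycycline in the 4 lines, in min in the short course (top) and in h in the long course (bottom). Points are libraries and lines join group means. Shf reached 45.6 TPM in the WT transgene line and 36.8 TPM in the KO transgene line at 330 min.

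**Figure D3:**
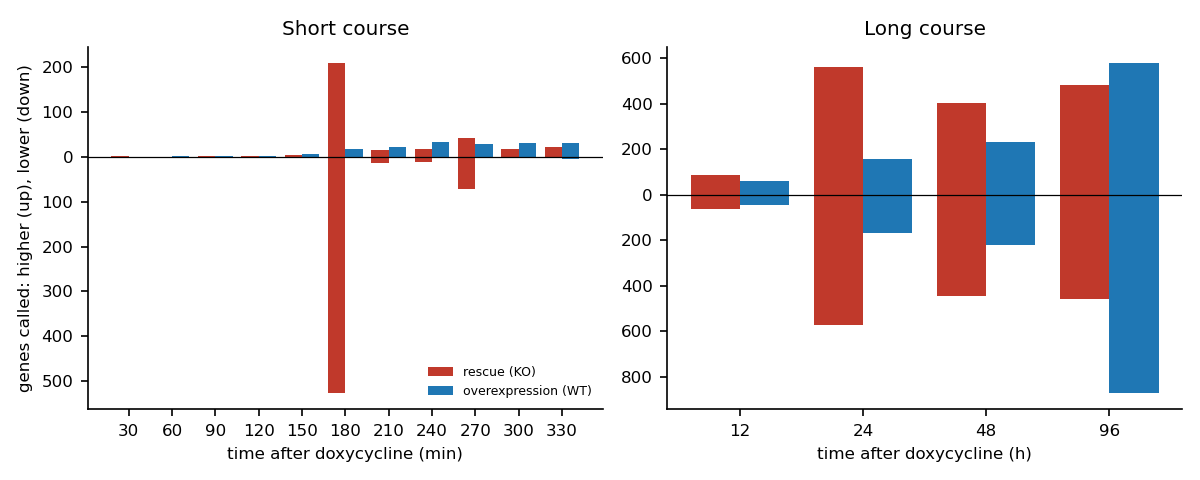
Number of genes called higher (bars up) and lower (bars down) at each time after doxycycline (min in the short, h in the long course), as the change from 0 min in the transgene line minus that in its control, for the rescue and the overexpression in both courses. The rescue peaked at 735 genes at 180 min of the short course.

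The difference between the rescue and the overexpression tests whether the response depends on the background. In the long course it called 934 genes (471 with the higher and 463 with the lower response in the KO background). The cyclin gene Ccnd2 (1.74 ± 0.37), the keratin gene Krt18 (1.09 ± 0.17) and the germ-cell gene Dazl (1.06 ± 0.10) had the higher response in the KO background, and Usp26 (-0.89 ± 0.19), Klf4 (-0.65 ± 0.07) and Cdkn1a (-0.54 ± 0.08) the lower (edgeR adjusted p = 4.29e-05, 3.25e-08, 2.36e-15, 1.27e-05, 1.62e-14 and 7.37e-08). Without replicate 1, 2 or 3 of every group 880, 233 and 304 genes were called, and 1 from 0 and 720 min alone. Imprinted genes had the higher response in the KO background (9 higher and 0 lower of 23, 12 and 0 adjusted over the list alone; camera adjusted p = 1.67e-06). Naive pluripotency genes (2 higher and 6 lower of 16, 2 and 8 adjusted over the list alone; camera adjusted p = 3.24e-04) and p53 targets (0 higher and 4 lower of 16, 1 and 5 adjusted over the list alone; camera adjusted p = 3.24e-04) had the lower response there, where the naive genes had fallen as a list. The imprinted genes and p53 targets each differed between a transgene line and its control at 0 min, which enters these responses too. The short course called 3 genes, Adgrg1 (-1.11 ± 0.37, edgeR adjusted p = 1.91e-05), Duox1 (0.10 ± 0.62, edgeR adjusted p = 0.00864) and the phosphatase gene Acp1 (0.21 ± 0.08, edgeR adjusted p = 0.0182), with 1992 genes at an unadjusted p under 0.05. The count depended on the method, with 123 genes called by DESeq2, 1 of them among these 3, and 564 by edgeR with no filter on low counts. Without replicate 1 of every group 219 genes differed and without replicate 2 1, and Adgrg1, Duox1 and Acp1 then stood at an edgeR adjusted p of 0.161, 0.255 and 0.253.

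The control lines show what changes without a transgene, where doxycycline, medium age and time in culture are 3 factors that the design does not separate. As no batch is named in the labels, differences between sets of libraries cannot be told apart from them either. In the KO control of the long course the imprinted growth genes H19 and Igf2 rose by 3.24 ± 0.17 and 2.83 ± 0.17, Cyp1a1 by 3.06 ± 0.50, the keratin gene Krt8 by 2.38 ± 0.07 and Asns by 0.95 ± 0.03, while Dppa3, a naive pluripotency gene, fell by 2.58 and the lactate transporter gene Slc16a3 by 2.18 (edgeR adjusted p = 5.28e-23, 3.29e-21, 3.17e-07, 1.10e-42, 1.95e-48, 3.13e-39 and 3.95e-35). In the WT control Usp26 fell by 1.86, Krt18 rose by 1.66 ± 0.08 and the Wnt target Axin2 by 0.94 ± 0.06 (edgeR adjusted p = 5.69e-35, 8.23e-33 and 1.51e-22). 10465 genes changed in the KO control (5232 higher, 5233 lower) and 9632 in the WT control (5047 higher, 4585 lower). Glycolysis and hypoxia genes fell in both (2 higher and 14 lower of 17, 2 and 14 adjusted over the list alone, in the KO control; camera adjusted p = 3.97e-16; WT control, camera adjusted p = 9.20e-14). The lactate dehydrogenase gene Ldha stood at -0.71 ± 0.03 and -0.57 ± 0.03. Cholesterol synthesis genes fell (2 higher and 17 lower of 20, 2 and 17 adjusted over the list alone, in the KO control; camera adjusted p = 2.69e-07; WT control, camera adjusted p = 1.55e-06). Mitochondrially encoded genes rose (13 higher and 0 lower of 13, 13 and 0 adjusted over the list alone, in the WT control; camera adjusted p = 1.54e-23; KO control, camera adjusted p = 1.70e-08, and adjusted p = 0.0537 with an estimated correlation). Of these, mt-Nd1 stood at 0.72 ± 0.05 in the WT control and 0.64 ± 0.05 in the KO control. Interferon response genes fell (0 higher and 7 lower of 9, 0 and 8 adjusted over the list alone, in the KO control; camera adjusted p = 9.95e-04).

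Over the short course 2390 genes changed in the KO control and 3918 in the WT control. Without replicate 1 or 2 of every group the counts were 791 and 1178 in the KO control and 3524 and 2252 in the WT control, and from the times to 150 min 135 in the KO control. In the WT control edgeR called 0 genes from the times to 150 min and 0 from 180 to 330 min, with 487 and 536 at an unadjusted p under 0.05, and DESeq2 was not run on these times. Cebpg, a partner of stress-response transcription factors, rose in the WT control by 0.63 ± 0.07, and Ppp1r10, a phosphatase-targeting subunit gene whose locus is a reported Firre contact, fell by 0.47 (edgeR adjusted p = 1.34e-21 and 1.34e-21). The list of Firre trans contacts was lower in that control (0 higher and 3 lower of 5, 0 and 3 adjusted over the list alone; camera adjusted p = 2.01e-05). In the KO control genes of the integrated stress response rose (7 higher and 0 lower of 20, 9 and 0 adjusted over the list alone; camera adjusted p = 3.79e-06; the stress-inducible Ddit4 0.47 ± 0.09). Immediate early genes were higher (7 higher and 1 lower of 16, 7 and 1 adjusted over the list alone; camera adjusted p = 2.36e-04, and adjusted p = 0.0569 with an estimated correlation). Between 150 and 180 min 456 genes changed in the WT control, 548 in the WT transgene line, 34 in the KO control and 388 in the KO transgene line. In the KO background more changed between 60 and 90 min, 64 in the control and 754 in the transgene line. At the other steps at most 5 genes changed in any line. As no culture or batch is named in the labels, libraries handled apart on either side of such a step cannot be told apart from a change with time. Across genes, the change of the same control over the long and the short course had a Pearson r of 0.0290 in the KO control and -0.0350 in the WT control. Genes are not independent replicates, so no p is given.

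**Figure D4:**
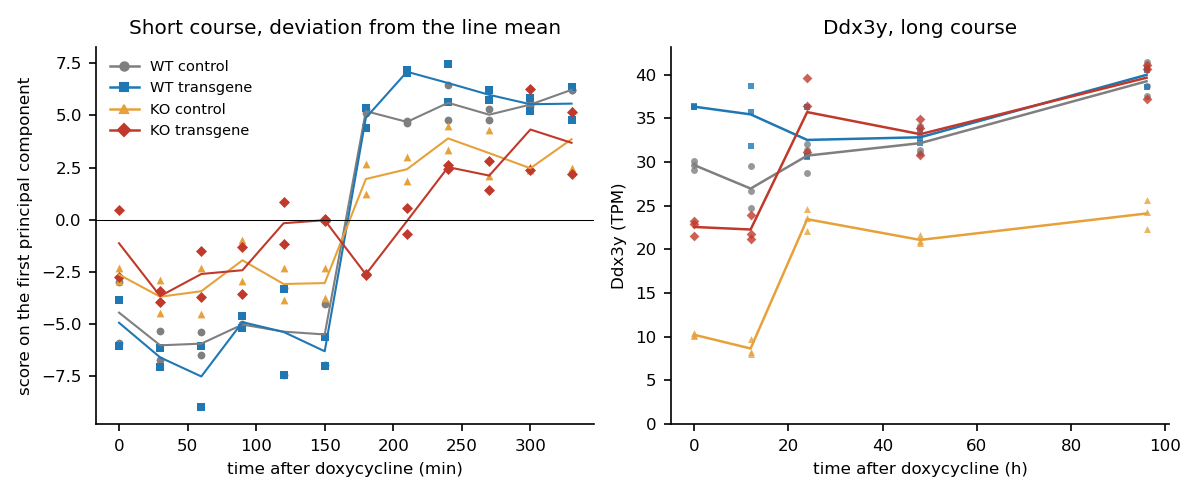
Left, score of each short-course library on the first principal component of its deviation from the line mean (18.1% of the variance) against time in min. Right, Ddx3y abundance in TPM against time in h in the long course. Points are libraries and lines join group means. The KO control went from 8.65 TPM at 720 min to 23.5 TPM at 1440 min.

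Whether putting Firre back reverses the knockout differences was tested across genes, with the knockout difference from one course and the rescue from the other so that no library was shared. Over the 6149 genes that differed between KO and WT in the long course, the knockout difference and the short-course rescue had a Pearson r of -0.119, a Spearman rho of -0.0280 and a covariance of -0.0169, and 52.4% had opposite signs. Of the 189 genes called in both, 106 had opposite and 83 the same direction. With the courses exchanged (1350 genes) r was -0.141, rho -0.100 and the covariance -0.0243, and 213 of 327 genes called in both had opposite directions. These genes include Firre, the gene deleted and put back. Without Firre, left out after the data were seen, r was -0.0580, rho -0.0280 and the covariance -0.00747, and with the courses exchanged -0.0450, -0.0980 and -0.00667, so most of each covariance came from that 1 gene. The directions hardly moved, with 106 of 189 and, exchanged, 212 of 326 genes called in both opposite. With the knockout difference over all times and without Firre, rho was -0.0410 (126 of 241 opposite) and, with the courses exchanged, -0.175 (878 of 1379 opposite). Suz12, higher in the KO control in both courses, was not called in the long or the short rescue (edgeR adjusted p = 0.973 and 0.0804).

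Several other lists missed the camera threshold in the long rescue. Primitive endoderm genes (5 higher and 2 lower of 14, 5 and 2 adjusted over the list alone, of 14; camera adjusted p = 0.330) did not pass as a list, with the collagen gene Col4a1 at 0.70 ± 0.08. The 2-cell-like state genes did not pass either (1 higher and 8 lower of 14, 1 and 9 adjusted over the list alone, of 14; camera adjusted p = 0.0539). Heat shock genes (3 higher and 0 lower of 12, 4 and 0 adjusted over the list alone, of 12; camera adjusted p = 0.330) did not pass. Wnt/beta-catenin targets (0 higher and 4 lower of 15, 2 and 5 adjusted over the list alone, of 15; camera adjusted p = 0.822) and G2/M genes (2 higher and 0 lower of 16, 4 and 0 adjusted over the list alone, of 16; camera adjusted p = 0.0633) missed the threshold too. The Wnt target Cdx1 fell by 0.65 and the heat shock gene Hsph1 rose by 0.19 ± 0.04 (edgeR adjusted p = 2.64e-06 and 3.93e-06). The camera adjusted p was 0.952 for mesendoderm, 0.634 for neuroectoderm, 0.453 for mitochondrial protein quality control, 0.967 for replication-dependent histones and 0.426 for the X inactivation centre. It was 0.999 for G1/S genes and 0.678 for the neighbours of the Firre locus, lists whose median and test differed in sign. Nuclear matrix and chromatin partners of Firre were lower in the long overexpression (0 higher and 4 lower of 13, 0 and 5 adjusted over the list alone, of 13; camera adjusted p = 0.0352, and adjusted p = 0.553 with an estimated correlation). The Polycomb gene Eed stood at -0.26 ± 0.04 and the cohesin gene Stag2 at -0.20 ± 0.06 (edgeR adjusted p = 3.16e-05 and 5.65e-04, and 0.118 and 0.124 without replicate 2). Over the 14 comparisons, 96 pairs of list and comparison passed, and 52 with an estimated correlation.

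**Figure D5:**
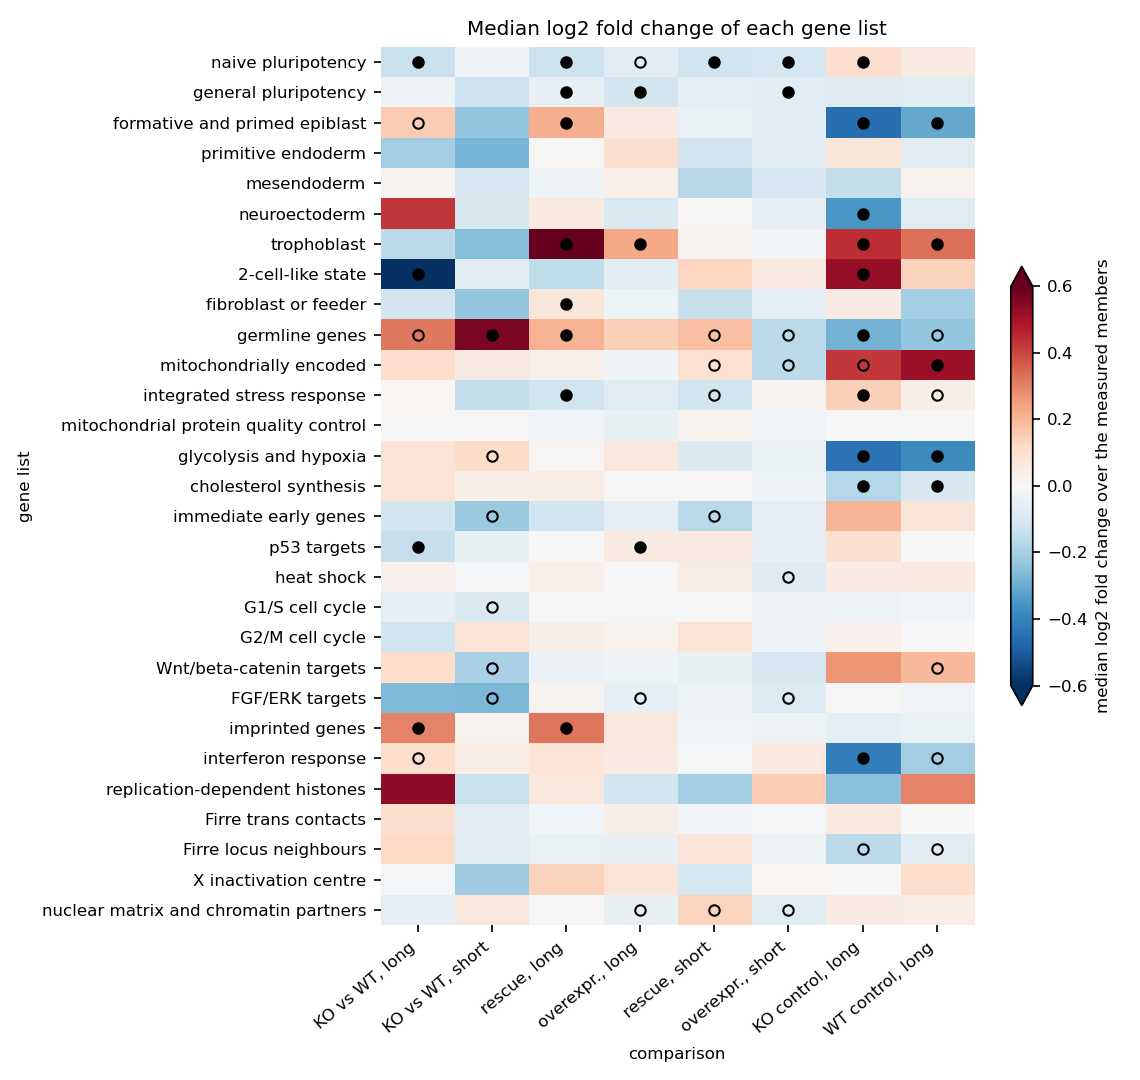
Median log2 fold change of each gene list (colour) in 8 comparisons, with a circle where the camera test passed. Filled circles passed also with an estimated correlation and open ones only with the preset correlation. Naive pluripotency genes had a negative median in the rescue and the overexpression of both courses.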

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

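Tests chosen only after the result was seen were those of neighbouring genes, those of doxycycline or time and of fewer cells with a Y chromosome for the Y-linked genes, and the splits of the libraries for KO against WT, the rescue in both courses, the KO control in both courses and the difference of responses in both courses.

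The response to the transgene differed between the KO and WT backgrounds for 934 genes in the long course. By the edgeR test of the difference, Firre differed by 4.74 ± 0.41, Ccnd2 by 1.74 ± 0.37, Rassf4 by 1.56 ± 0.35, Dcdc2a by 1.52 ± 0.37 and S100a6 by 1.48 ± 0.28, and in the other direction Mip by -1.95 ± 0.42, Gpd1 by -1.78 ± 0.37, Cap2 by -1.76 ± 0.32 and Padi3 by -1.52 ± 0.33. With replicate 1 of every group left out, the edgeR adjusted p was 0.209 for Rassf4 and 0.118 for Gpd1. Without replicate 2 it was 0.151 for Rassf4, 0.252 for Dcdc2a, 0.330 for Mip, 0.0522 for Gpd1, 0.128 for Cap2 and 0.126 for Padi3, and without replicate 3 0.131 for Rassf4, 0.117 for S100a6, 0.126 for Mip and 0.345 for Gpd1. DESeq2 gave Mip no adjusted p in that comparison, nor Duox1 and Adgrg1 in that of the short course. Among lists, imprinted genes (camera adjusted p = 1.67e-06) and formative and primed epiblast genes (camera adjusted p = 0.0169, and adjusted p = 0.143 with an estimated correlation) differed one way and naive pluripotency genes (camera adjusted p = 3.24e-04) and p53 targets (camera adjusted p = 3.24e-04) the other. Trophoblast genes (camera adjusted p = 0.0175) and FGF/ERK targets (camera adjusted p = 0.0494, and adjusted p = 0.358 with an estimated correlation) passed too. In the short course 3 genes differed by the test of the curves, Acp1 by 0.21 ± 0.08, Duox1 by 0.10 ± 0.62 and Adgrg1 by -1.11 ± 0.37. The lists that differed there were germline genes (camera adjusted p = 0.00266, and adjusted p = 0.138 with an estimated correlation), mitochondrially encoded genes (camera adjusted p = 5.76e-05, and adjusted p = 0.284 with an estimated correlation), G2/M genes (camera adjusted p = 0.0416, and adjusted p = 0.293 with an estimated correlation) and nuclear matrix and chromatin partners (camera adjusted p = 1.53e-07, and adjusted p = 0.284 with an estimated correlation).

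Duox1 and Shf, which rose together in both backgrounds, lie on chromosome 2 with their 3' ends facing each other and a gap of 919 bp between the annotated genes, so overlap of the annotated genes is excluded as the source of the shared rise. The 34 genes higher in all 4 responses held 4 non-overlapping pairs with a gap of at most 100 kb. Without Duox1 and Shf, the pair that prompted the test, 3 pairs remained, 2 of them sharing Ppp1r2, and 2 of 10000 random gene sets held as many (a share of 3e-04 with the real set counted), which argues against chance for the other neighbours of the set and leaves it open for this pair. Both genes passed in 2 of 2 transgene lines, and as the sites of the transgenes are not given, an insertion beside them cannot be told apart from an effect of Firre on the region. Because the libraries do not mark strand, Shf transcripts that run on into Duox1 stay open as a source of the Duox1 counts and were not tested.

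In the long course the largest number of changes, 10313 genes by the mean of the 4 lines, lay between 720 and 1440 min, and in the KO control the Y-linked genes Ddx3y, Uty and Eif2s3y rose with it. The median change of the 4 Y-linked genes examined first was 1.13 in the KO control, 0.66 in the KO transgene line and 0.10 in the WT control over the same step, which argues against doxycycline or time in culture acting on these genes alike in both backgrounds. If fewer cells held a whole Y chromosome at 0 and 720 min, every Y-linked gene would rise between 720 and 1440 min. In the KO control Uba1y, also examined first, changed by 0.06 ± 0.11 and Kdm5d and Zfy1 by -0.13 ± 0.19 and -0.11 ± 0.18. The mean of all 7 genes not examined first, weighted by precision, was -0.063 ± 0.08. These values argue against fewer cells with a whole Y chromosome and do not cover a part of it. Among the 7 genes Gm29650 rose by 2.27 ± 0.74 (edgeR adjusted p = 0.0106) and Usp9y by 1.12 ± 0.65, both with a mean log2 CPM under -1. The median of these 7, -0.034, with a range from -0.19 to 2.27, does not decide whether the libraries came from other cultures, which can differ in genes that are not Y-linked, and as no culture or batch is named in the labels, other cultures cannot be told apart from a change with time in the KO lines.

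The peak of 735 rescue calls at 180 min of the short course depended on 1 library among those left out in turn. Without replicate 1 of the KO transgene line at 180 min 29 genes were called at that time, and without replicate 2 1272, where the library left is assumed to vary like the other groups, so a fault of replicate 1 fits but is not shown. Both replicates of that group scored alike on the first principal component of the course, -2.58 and -2.64, below every other library from 180 min on, so part of the deviation was shared. The KO control at 180 min enters the same contrast, and its replicates differed most of all pairs of the short course. Their chi-square per degree of freedom against sampling noise was 35.7, against 12.3 for the KO transgene pair at 180 min and a median of 6.17. The 10 most abundant genes took 7.34% of the counts in replicate 2 of the KO control at 180 min and 6.14% in replicate 1. Whether a few abundant genes carried that chi-square was not tested. No KO control library was left out, so a fault there was not tested. Of the genes called, 29.8% had the same direction at 180 min in the WT background (42.9% of all genes), which argues against a common effect of Firre. Across genes, the change from 150 to 180 min in the WT control had an r of 0.706 with that in the WT transgene line, 0.418 with the KO control and 0.00984 with the KO transgene line, so a step that this line did not share stays open, but 61.1% of the genes called went against the step of the WT control (52.7% of all genes), a value between the bounds set, so it cannot be told apart from the 1 library.

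Other splits of the same libraries were fitted with edgeR on the lines compared. For KO against WT, and for the transgene line against the control at 0 min in the KO and WT backgrounds, the 10 splits are too few for a share under 0.05. The real split, 1 of 10 each time, called 6680, 415 and 2765 genes and the highest other 0 (450 at an unadjusted p under 0.05), 4 and 1. Chance can be excluded for the KO and WT controls of the long course (1 of 100 each; 10553 and 5540, 8857 and 2478) and of the short course (1 of 100 each; 1876 and 7, 4028 and 1). The real split also called the most genes for the long rescue (1 of 100; 1976, highest other 1533) and overexpression (1 of 100; 1463 and 1297). The same holds for the short rescue (1 of 60; 105 and 62) and overexpression (1 of 60; 216 and 67). Splits that call so many genes point to a structure of the samples. At an unadjusted p under 0.05 the real split led only for the long rescue (4058 genes, highest other 3844). Another split was above it for the long overexpression (4032 against 3869), the short rescue (2547 against 2137) and the short overexpression (3135 against 2139). These splits mixed transgene and control libraries, whose lines can differ before induction. Chance is thus not firmly excluded for these responses. For the difference of responses, 2 of 60 splits were as large in the long course (934 genes, highest other 1291). That share is under 0.05 but rests on few splits. A split above the real one points to structure, so chance is not firmly excluded. For the short course 2 of 40 were as large (3 genes, highest other 3), and chance cannot be excluded.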

How the results depend on the processing

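Settings that leave out times, single libraries or Firre, and the lists at 720 min alone, were chosen after seeing the data. Where no reason is given, the cause was not tested. With a minimum log2 fold change of 0.58, fewer genes pass by construction, 1391 for the long KO comparison, 283 for the short KO comparison, 78 for the KO transgene line at 0 min, 351 for the WT transgene line at 0 min, 470 for the long rescue, 221 for the long overexpression, 24 for the short rescue, 25 for the short overexpression, 2773 for the KO control of the long course, 1691 for the WT control of the long course, 67 for the KO control of the short course, 142 for the WT control of the short course, 266 for the long difference of responses and 1 for the short difference of responses. Leaving out 1 replicate number of every group gave 4664 to 4956 for the long KO comparison, 248 to 319 for the KO transgene line at 0 min, 1090 to 1455 for the WT transgene line at 0 min, 742 to 1271 for the long rescue, 297 to 1658 for the long overexpression, 52 to 325 for the short rescue, 51 to 799 for the short overexpression, 8226 to 8882 for the KO control of the long course, 7443 to 8158 for the WT control of the long course, 791 to 1178 for the KO control of the short course, 2252 to 3524 for the WT control of the short course, 233 to 880 for the long difference of responses, 1 to 219 for the short difference of responses. In the short course this left 1 library per group, which the smooth curve pools over times, and the short KO comparison, with no residual df then, was not run. Without a filter on low counts the tests called 1131 for the short rescue, 469 for the short overexpression and 564 for the short difference of responses. DESeq2 called 572 for the short rescue and 123 for the short difference of responses, the latter with 81.3% higher in the KO background against 66.7% with edgeR. A fit on only the lines compared called 105 for the short rescue and 216 for the short overexpression, 1 coefficient per time 171 for the short rescue, 46 for the short overexpression, 1031 for the KO control of the short course and 2021 for the WT control of the short course, and a spline with 5 df 82 for the short overexpression. DESeq2 size factors and a minimum mean of 50 counts moved no count of these tests by over 1.5 times.

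Over all 12 times the short KO comparison called 8239 genes, with more libraries in the contrast. With 0 and 720 min alone the counts were 126 for the long rescue, 86 for the long overexpression, 1560 for the KO control of the long course, 826 for the WT control of the long course and 1 for the long difference of responses, and with 1440 to 5760 min alone 319 for the long rescue, 94 for the long overexpression, 3467 for the KO control of the long course, 5339 for the WT control of the long course and 105 for the long difference of responses. With 0 to 150 min alone they were 5 for the short rescue, 5 for the short overexpression, 135 for the KO control of the short course, 0 for the WT control of the short course and 0 for the short difference of responses, and with 180 to 330 min alone 188 for the short rescue, 1 for the short overexpression, 30 for the KO control of the short course, 0 for the WT control of the short course and 0 for the short difference of responses. The counts of 0 are from edgeR and DESeq2 was not run on these times. At an unadjusted p under 0.05 the WT control had 487 genes at 0 to 150 min and 536 at 180 to 330 min, and the difference of responses 479 and 1209. Without the 180 min libraries the short rescue called 148 genes, and without replicate 1 of the KO transgene line at 180 min 210 and without its replicate 2 235. The short difference of responses called 5 genes without replicate 1 and 5 without replicate 2 of that group. The difference of Duox1, 0.10, was -0.89 without replicate 2 and 0.88 without replicate 1. Without replicate 3 of the WT control at 1440 min the long overexpression called 1662 genes and the long difference of responses 892. With an estimated correlation 52 pairs of list and comparison passed, against 96. The correlation of the knockout difference with the rescue, -0.119, was -0.141 with the courses exchanged, -0.0900 with the knockout difference over all times and -0.150 with both. Without Firre, the gene deleted and put back, these were -0.0580, -0.0450, -0.0390 and -0.120, so Firre carried much of the first 3. Every direction of a named gene held under DESeq2, both scalings and both filters. DESeq2 gave 5 results of named genes no adjusted p, and 1 missed the threshold with the lines compared alone.

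The replicate numbers were not taken to pair the samples, because the labels give a number no shared origin and the correlations ran both ways. The deviations of libraries with the same number and course from their group means had a median r of 0.0212 in the long course (-0.623 to 0.683) and 0.0766 in the short course (-0.558 to 0.687). Of the libraries, 33 of 60 and 76 of 96 correlated best with their own number, out of 3 numbers in the long and 2 in the short course. This hints that libraries of a number deviated together. In the short course the 2 deviations of a group mirror each other, so the 96 libraries do not count separately. With the replicate number as a block the counts were 6313 for the long KO comparison, 1621 for the short KO comparison, 684 for the KO transgene line at 0 min, 2458 for the WT transgene line at 0 min, 2212 for the long rescue, 2039 for the long overexpression, 434 for the short rescue, 157 for the short overexpression, 10613 for the KO control of the long course, 9762 for the WT control of the long course, 2731 for the KO control of the short course, 4173 for the WT control of the short course, 1146 for the long difference of responses, 3 for the short difference of responses, none moved by over 1.5 times, and 97 pairs of list and comparison passed.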

Other observations

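The genes named next, and the tests of the Fgfbp3 region, were chosen after the values were seen. For genes higher in all 4 responses, the mean log2 fold changes over the times after 0 min, in the order long rescue, long overexpression, short rescue and short overexpression, were 0.64, 0.59, 0.32 and 0.24 for Umps, which makes uridine monophosphate, and 1.26, 0.94, 0.25 and 0.41 for Impdh1, which acts in guanine nucleotide synthesis. They were 0.55, 0.43, 0.34 and 0.20 for the lymphatic growth factor gene Vegfc and 0.45, 0.29, 0.28 and 0.15 for the osteopontin gene Spp1, which overlaps a gene model with a provisional symbol, so their reads cannot be separated. The chromatin remodelling subunit gene Dpf2 stood at 0.70, 0.69, 0.29 and 0.38 and the nucleoside transporter gene Slc29a3 at 0.81, 0.89, 0.30 and 0.56. Among those lower in all 4, the Nodal inhibitor gene Lefty2 stood at -0.24, -0.26, -0.24 and -0.12.

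Fgfbp3 rose in the WT transgene line within the first times, with a mean log2 fold change over 30 to 90 min of 2.00 ± 0.33 (edgeR adjusted p = 5.70e-04), against 0.04 ± 0.39 in the KO background. The difference between the responses did not pass over the short course (-1.98 ± 0.46, edgeR adjusted p = 0.523), and in the long course Fgfbp3 stood at 1.19 ± 0.248 TPM in the WT transgene line at 0 min and 1.03 ± 0.0330 at 720 min (SD, n = 3). Over all times of the short course its neighbour Btaf1 differed between the WT transgene line and its control by -0.43 ± 0.02 and Ide by 0.56 ± 0.02, against 0.01 ± 0.02 and -0.03 ± 0.02 in the KO background. A candidate explanation is that the transgene lies beside Fgfbp3 in the WT transgene line. Of 12 genes within 500 kb, 3 differed by a log2 fold change of at least 0.4 in that line, and a share of 0.0694 of windows around other genes held as many, more than 0.05, so an insertion cannot be told apart from the differences that lines show elsewhere. Of those that differed, 0 reached that size in the KO transgene line by edgeR, which argues against an insertion there in both lines.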
